A study of Mus musculus with 2 samples.

How the data were processed

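The data are 2 single-cell RNA-seq libraries of sorted TdTomato-positive cells from peripheral retina of mouse embryos at stage E13.5, 1 pigmented and 1 albino, each from 3 pooled embryos. Tissue was dissociated with papain and libraries were made with a droplet 3' kit of the v2 type, per the labels' protocols. The deposited matrices hold raw UMI counts per gene and barcode, and their barcodes start at 500 and 501 UMIs, so they had been selected before deposit by a rule not given in the sources used here. The submitters' processing notes name Cell Ranger 2.1.1 and the mouse build mm10, while the matrix headers name Cell Ranger 5.0.1, and which version made the counts is unsettled. The matrices have 32285 genes. The TdTomato transcript was not examined. The groups come from the sample titles.

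Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, and doublets called by Scrublet (in Scanpy, run per library) were removed. Under 500 genes had 134 pigmented and 110 albino barcodes, and over 10% mitochondrial UMIs 188 and 136. Scrublet called 172 pigmented barcodes (2.82%) and 39 albino barcodes (1.06%). In the pigmented library 2.56% of the kept cells still carried both Xist and Y-linked UMIs, which doublets or free RNA can give. Counts were scaled to the cell total and log-transformed. The 2000 genes with the highest normalised dispersion (the lower of the 2 libraries' values), without mitochondrial, ribosomal protein and haemoglobin genes and without the 91 genes of the outcome lists (Ccnd2 included), gave 30 principal components. A graph of 15 neighbours weighted by shared neighbours was clustered by the Leiden method at resolution 1.0, with both libraries together and no batch correction. Software was Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, Scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9.

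The 14 marker lists were fixed before the data were examined. The rule that turns them into names was set after the clusters, their counts per library and first class ratios had been seen. A cluster took the class with the highest mean log2 fold of its markers over the other cells (pseudocount 10 CPM) if that mean led the next class by at least 0.3, if at least 3 markers were each detected in 10% of the cells, if no other class had more markers among the 10 leading genes, and if the median UMI count was not over 3 times below that of all cells. A margin of 0.5 was considered and put aside because RPC-like clusters 6 and 4 lost their name. A margin of 0.25 was then used for 1 run so that cluster 19, which misses 0.3 narrowly, took the name RPE-like (retinal pigment epithelium), and was withdrawn for that reason. Margins of 0, 0.25 and 0.5 are therefore among the alternatives. Of 20 clusters, 15 were named. The unnamed ones hold 19.0% of the pigmented and 16.7% of the albino cells. These are cluster 2 (9.05% and 8.43%, led by Gal, Dlx1 and Insm2), cluster 10 (4.54% and 3.77%, led by Pcdh17, Otx2 and Onecut1), cluster 12 (4.06% and 3.14%, led by crystallin genes, Acta2 and Pf4), cluster 17 (0.805% and 0.979%, shallow cells) and cluster 19 (0.508% and 0.403%, led by Pmel, Dct and Trpm1). Cluster 19 was examined for pigment genes after its values were seen. The mesenchyme-like cluster 13 also holds haemoglobin RNA. RPC-like cluster 6 has G2/M genes in the lead and may hold cycling cells of the CMZ.

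Shares of cells have exact Clopper-Pearson intervals. Gene levels are UMIs summed over the cells of a class per 1000000 UMIs of the same cells (CPM), with exact Poisson intervals, and ratios are albino over pigmented with the conditional exact interval. All intervals are at 95% and cover counting error only. They hold no difference between embryos, litters or library preparations, so no test between the groups was made. For shares of cells with a UMI each cell was thinned to 5800 UMIs, the 10th percentile of the library with the lower median. The choice of that library was read from the median after both were seen, and 5400 UMIs, from the albino library, is an alternative.

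Gene lists were fixed before the data were examined. Members with at least 20 UMIs over both libraries were used, log2 ratios were computed after adding 1 UMI per library, and the list median was placed among the medians of 10000 random lists of the same size, drawn with replacement from the same 20 bins of expression. Marker lists were placed among random lists over all cells only, since they also name the clusters. Within their own class only counts and medians are given for them. The values of 1 list member are not reported here. Named genes are the 10 with the largest and the 10 with the smallest ratio over all cells and the first 5 each way within 4 classes, ranked by the bound of the interval nearest to 1 among genes with at least 50 UMIs. Mitochondrial, ribosomal protein, haemoglobin, sex and gene-model genes were left out of that ranking. They took 1.92% (mitochondrial), 23.8% (ribosomal protein) and 0.00696% (haemoglobin) of the pigmented UMIs and 1.54%, 23.3% and 0.000323% of the albino UMIs, and gene models 1.66% and 1.64%. From the lists, genes with many UMIs or a large ratio were named, and all members of the pigment list and of the axon laterality list with at least 20 UMIs. Positions are from GENCODE M21 on GRCm38, matched by gene identifier (75 of 75 found).

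The ratio and ranking steps were tested on simulated counts with the real means and totals and 200 genes altered by known folds. Over all cells (14525 genes) the interval held the true ratio for 95.5% of unaltered genes, and 91.9% of genes altered 1.5-fold and 100.0% of those altered 2.0-fold were recovered. In CMZ-like cells (10685 genes) these were 95.7%, 80.0% and 100.0%, and in RPC-like cells (12037 genes) 95.7%, 82.9% and 95.8%, where the interval held the true ratio for 88.6% of genes altered 1.5-fold. The simulation has counting error alone.

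Alternatives fixed before the data were examined were other filters on cells, other clustering settings, classes from marker scores, other scalings, weighting each cell equally, and other UMI minima. Added after the data were seen were cells with Xist and without Y-linked UMIs, clustering without cell cycle genes, clustering without class markers, shares over retinal cells alone, the naming margins and the second thinning depth.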

Results

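Single-cell RNA sequencing was carried out on mouse peripheral retina at stage E13.5. The α-Cre transgene, which acts in the peripheral retina, switched on the red fluorescent protein TdTomato, and labelled cells were sorted by flow cytometry. The tissue includes the ciliary margin zone (CMZ), the rim of the optic cup next to the neural retina. There was 1 pigmented and 1 albino library, each from 3 pooled embryos. The pigmented library carries the strain label Tyrc2j, a name known for an albino allele of the tyrosinase gene, which conflicts with its title. The titles were followed here, and if the 2 libraries were exchanged every ratio of albino over pigmented below would turn around. If instead the label held for that library and its title did not, both libraries could be albino. The ratios would then not compare pigmentation. The albino library carries the label Swizz ICR, so pigmentation goes together with strain, pool and library. The pigmented matrix held 6089 barcodes and 69965728 unique molecular identifiers (UMIs), and the albino matrix 3676 barcodes and 46271969 UMIs. After filtering, 5711 pigmented cells with a median of 10319 UMIs and 3474 albino cells with a median of 11194 UMIs were kept. With 1 library per group there is no replicate check, no test and no p-value, and all intervals are exact 95% intervals for counting error only. The pools also differed in sex. In the pigmented library 46.1% of cells carried Y-linked UMIs without Xist and 29.3% carried Xist without Y-linked UMIs. In the albino library 96.1% carried Xist without Y-linked UMIs, and 3 cells carried any Y-linked UMI.

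The first comparison asked how the cell types of the peripheral retina were distributed in the 2 libraries. Retinal ganglion cell (RGC)-like cells, the first neurons of the retina, made up 19.9% of the albino cells (691 cells, interval 18.6% to 21.3%) and 9.81% of the pigmented cells (560 cells, 9.05% to 10.6%), a ratio of 2.03 (1.81 to 2.27). CMZ-like cells made up 8.81% of the albino cells (306 cells, 7.89% to 9.80%) and 12.8% of the pigmented cells (729 cells, 11.9% to 13.7%), a ratio of 0.690 (0.602 to 0.790). Retinal progenitor cell (RPC)-like cells were 32.9% of the albino and 37.8% of the pigmented cells, a ratio of 0.871 (0.810 to 0.936). Neurogenic-like cells, which express Atoh7 and Notch ligands, were 9.27% and 9.65%, a difference within the counting intervals.

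Both RGC-like clusters were larger in the albino library, with ratios of 1.84 and 2.40. Of the CMZ-like clusters, the larger one, cluster 5, had a ratio of 0.606 (0.509 to 0.719) and cluster 11 a ratio of 0.872 (0.694 to 1.09). Photoreceptor-like cells were 3.14% of the albino and 3.94% of the pigmented cells, and amacrine or horizontal-like cells 2.25% and 2.45%. Surface ectoderm-like cells were 2.59% of the albino and 0.473% of the pigmented cells, in a cluster made up mostly of the albino library, while 90.7% of the pigmented UMIs of the keratin gene Krt15 lay in the unnamed cluster 12. The unnamed clusters held 16.7% of the albino and 19.0% of the pigmented cells. The RPC-like difference was close to 0 on the log2 scale with a minimum of 1000 genes per cell (log2 ratio -0.03) and with a stricter naming margin of 0.5 (-0.02). The CMZ markers themselves were lower within the albino CMZ-like cells, in 10 of 10 measured markers (median log2 ratio -0.31), and some of these genes set the clusters. Clustering without any class marker gave log2 ratios of the shares of -0.52 for CMZ-like and 1.0 for RGC-like cells, beside -0.54 and 1.02 with them, and -0.18 for RPC-like cells.

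**Figure D1:**
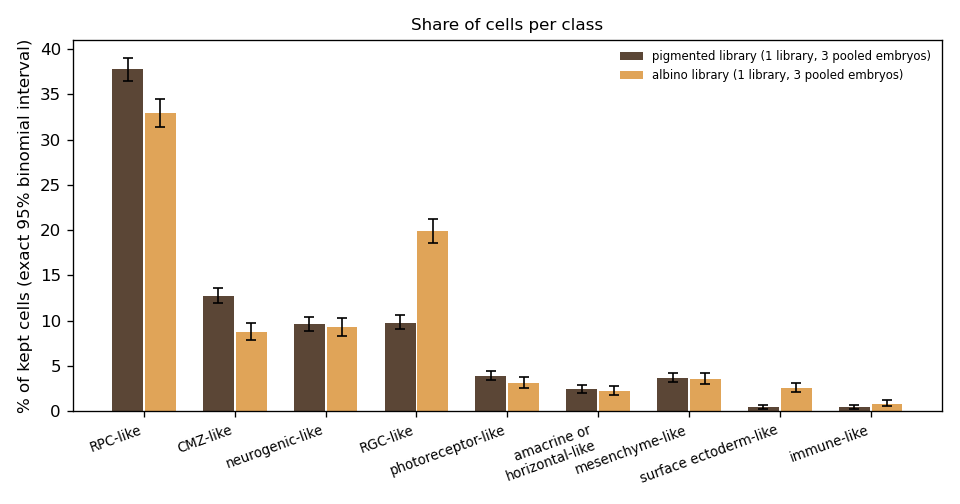
Share of kept cells per class in % for the pigmented and the albino library, with exact 95% binomial intervals as error bars (counting error only, 1 library per bar). RGC-like cells stand at 19.9% in the albino and 9.81% in the pigmented library, and CMZ-like cells at 8.81% and 12.8%.

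The second comparison concerned Ccnd2, which encodes cyclin D2, a G1 cyclin and the gene named in the title of the series. Ccnd2 (ENSMUSG00000000184) lies on chromosome 6 at 127125162 to 127152193 on the minus strand of GRCm38, where its exons overlap those of 9330179D12Rik and Gm43126 on the opposite strand. Whether the counting used strand is not given in the sources used here. Over all cells, Ccnd2 stood at 90.9 counts per 1000000 UMIs (CPM) in the pigmented and 55.7 CPM in the albino library, a ratio of 0.612 (0.584 to 0.642). Within CMZ-like cells it stood at 291 CPM (3034 UMIs) and 219 CPM (986 UMIs), a ratio of 0.752 (0.699 to 0.808). Within RPC-like cells it stood at 51.8 and 44.3 CPM, a ratio of 0.855 (0.775 to 0.942), and within neurogenic-like cells at 16.4 CPM (97 UMIs) and 7.59 CPM (28 UMIs), a ratio of 0.463 (0.293 to 0.711). Outside the retina it stood at 366 and 383 CPM in mesenchyme-like cells, a ratio of 1.05 (0.948 to 1.15), and at 56.3 (18 UMIs) and 14.6 CPM (48 UMIs) in surface ectoderm-like cells, a ratio of 0.260 (0.148 to 0.475). In photoreceptor-like cells, which are retinal, it stood at 25.1 and 25.9 CPM, a ratio of 1.03 (0.608 to 1.72).

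Among the retinal classes Ccnd2 was highest in CMZ-like cells in both libraries, at 5.62 times the RPC-like level in the pigmented library (5.26 to 6.01) and 4.95 times in the albino library (4.47 to 5.48). Ccnd1 (ENSMUSG00000070348, chromosome 7, 144929931 to 144939925, minus strand, with exons that overlap those of LTO1 on the opposite strand), the cyclin D1 gene, had the opposite distribution, with CMZ-like over RPC-like ratios of 0.413 (0.402 to 0.425) and 0.508 (0.489 to 0.527). For Ccnd3 (ENSMUSG00000034165, chromosome 17, 47505051 to 47599691, plus strand, overlapping Bysl likewise) these ratios were 1.12 (1.05 to 1.20) and 1.05 (0.9498 to 1.16), of which only the albino one is within counting error of 1. With each cell thinned to 5800 UMIs, a Ccnd2 UMI was found in 66.1% of pigmented CMZ-like cells (62.4% to 69.6%) and in 51.9% of albino CMZ-like cells (46.0% to 57.8%). At full depth these shares were 81.8% and 67.3%. In RPC-like cells the thinned shares were 14.4% and 14.3%. RGC-like cells, which have left the cell cycle, gave 1.47% and 0.458% after thinning and 3.21% and 0.724% at full depth, with median depths of 14172 and 14484 UMIs against 13549 and 12626 in CMZ-like cells. Thinning left out 546 pigmented and 387 albino cells. The RPC-like ratio of Ccnd2 was near 0 on the log2 scale among cells that carry Xist and no Y-linked UMI (log2 ratio -0.03) and with classes taken from marker scores (-0.01). The neurogenic-like log2 ratio of -1.11 came to -0.28 when cell cycle genes were left out of the clustering.

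**Figure D2:**
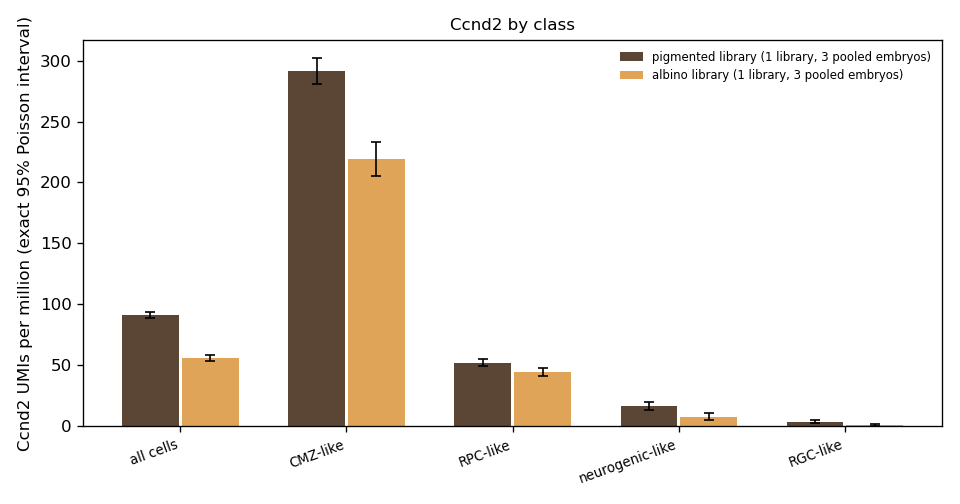
Ccnd2 level in UMIs per 1000000 UMIs over all cells and within 4 classes of the pigmented and the albino library, with exact 95% Poisson intervals as error bars (counting error only, 1 library per bar). CMZ-like cells hold 291 CPM in the pigmented and 219 CPM in the albino library, and RPC-like cells 51.8 and 44.3 CPM.

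The cell cycle lists were lower in the albino library over all cells and not within its CMZ-like cells. Their levels over all cells also follow the class shares, and RGC-like cells, which have left the cell cycle, had a higher share there. Random lists matched on expression do not allow for this. Of the G1/S regulators, 13 of 15 were lower over all cells (median log2 ratio -0.19), among them Ccnd1 (765 and 609 CPM in the pigmented and albino library), Ccnd3 (84.5 and 68.3 CPM) and the cell cycle inhibitor gene Cdkn1c (316 and 277 CPM). All 18 S phase genes were lower (median -0.19, below all 10000 random lists matched on expression), such as the replication helicase gene Mcm7 (200 and 165 CPM). Of the G2/M genes, 17 of 18 were lower (median -0.18, or -0.07 with every cell weighted equally), such as Top2a (398 and 339 CPM). Within CMZ-like cells, 17 of 18 S phase genes (median 0.19) and 17 of 18 G2/M genes (median 0.29) were higher in the albino library. Over other settings these medians ran from 0.08 to 0.29 and from 0.27 to 0.32. The proliferation marker Mki67 stood at 106 and 142 CPM and Ccnd1 at 579 and 698 CPM, while Ccnd2 and Cdkn1c (619 and 499 CPM) were lower. A single albino cell held 13.1% of the class's Mki67 UMIs. Cluster 11 held 31.6% of the pigmented and 39.9% of the albino CMZ-like cells. Within cluster 5 the S phase median was 0.05 and the G2/M median -0.39, and within cluster 11 they were -0.01 and -0.04, so neither cluster on its own had the higher G2/M level of the class. Ccnd2 was lower in both, with ratios of 0.806 (0.733 to 0.885) in cluster 5 and 0.776 (0.690 to 0.872) in cluster 11. Within RPC-like cells the S phase and G2/M medians were 0.02 and -0.05, the latter from -0.19 to -0.01 over other settings. Within neurogenic-like cells 17 of 18 G2/M genes were higher (median 0.16), while the S phase and G1/S medians were -0.03 and -0.15. These genes were not split by cluster there. Neurogenic-like cluster 8 held 259 of the 551 pigmented and 184 of the 322 albino cells of that class.

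Of the differentiation markers, those of RGCs differed most. These lists are also the markers that name the classes. Their levels over all cells therefore follow the class shares, and their place among random lists adds no separate support. Over all cells 12 of 12 RGC genes were higher in the albino library (median log2 ratio 0.84, above all 10000 random lists), with the synuclein gene Sncg at 331 and 775 CPM and the neurofilament gene Nefl at 240 and 533 CPM in the pigmented and albino library. All 11 neurogenic factors were lower (median -0.22), with Neurog2 at 92.5 and 72.2 CPM but Atoh7 at 1801 and 1708 CPM, while within neurogenic-like cells 8 of 11 were lower with a median of -0.03. Of 10 CMZ markers 9 were lower (median -0.34), led by the homeobox gene Msx1 at 6.87 and 2.12 CPM and the connexin gene Gja1 at 55.6 and 32.4 CPM. Of 10 RPC markers 9 were lower (median -0.23), with Six3 the exception (301 and 331 CPM), while within RPC-like cells 5 were lower and 5 higher (median -0.02). Within RGC-like cells 9 of the 12 RGC genes were higher (median 0.09). Over all cells 7 of 8 photoreceptor precursor genes were lower (median -0.22). Of 7 amacrine or horizontal genes 5 were higher (median 0.35), among them Onecut2 (163 and 211 CPM), while Ptf1a was lower (18.9 and 15.3 CPM).

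Of the signalling lists, 14 of 15 Wnt genes (median -0.27), 10 of 12 Notch genes (-0.24), 10 of 11 Hedgehog genes (-0.28) and 10 of 11 BMP genes (-0.15) were lower over all cells in the albino library. Some members, such as Wls, Sfrp2, Msx1, Hes1 and Dll1, are also class markers. Levels over all cells also follow the shares of the classes, and within RPC-like cells the medians were -0.03 for Wnt, -0.09 for Notch, -0.11 for Hedgehog and 0.07 for BMP. Within CMZ-like cells they were -0.07 for Wnt, 0.26 for Notch, -0.05 for Hedgehog and 0.08 for BMP, and that for Notch came to 0.03 with every cell weighted equally. Of the Wnt genes, Axin2 had a ratio of 0.568 (0.358 to 0.872) there but Fzd5 1.37 (1.20 to 1.55), Dkk3 1.14 (1.05 to 1.24) and Sfrp2 1.11 (1.08 to 1.15). The top albino cell for each gene held 7.41% (Axin2), 11.3% (Fzd5), 7.32% (Dkk3) and 4.65% (Sfrp2) of the class's UMIs. The BMP median over all cells lay within the middle 95% of random lists. In the glycolysis and hypoxia list 9 genes were higher and 5 lower over all cells, with Bnip3 at 37.5 and 51.5 CPM but the glucose transporter gene Slc2a1 at 145 and 111 CPM. Its median of 0.12 lay above the middle 95% of random lists, but the interval over members, -0.11 to 0.24, included no change. Within classes that interval excluded no change in RPC-like (median 0.11, 0.06 to 0.26, 12 of 14 higher) and RGC-like cells (0.18, 0.03 to 0.31, 11 of 13). It included no change in CMZ-like (0.09, 9 of 14 higher) and neurogenic-like cells (-0.01, 7 of 14). Immediate early and stress genes were lower in 12 of 14 members (median -0.23, below all random lists), with Fos at 260 and 165 CPM and Fosb at 106 and 60.2 CPM. That list's median was also negative within RPC-like (-0.20, 13 of 14 lower), neurogenic-like (-0.34, 10 of 11) and RGC-like cells (-0.21, 11 of 12). Within CMZ-like cells it was -0.19 with 10 of 14 lower, and the interval over members, -0.37 to 0.09, included no change.

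**Figure D3:**
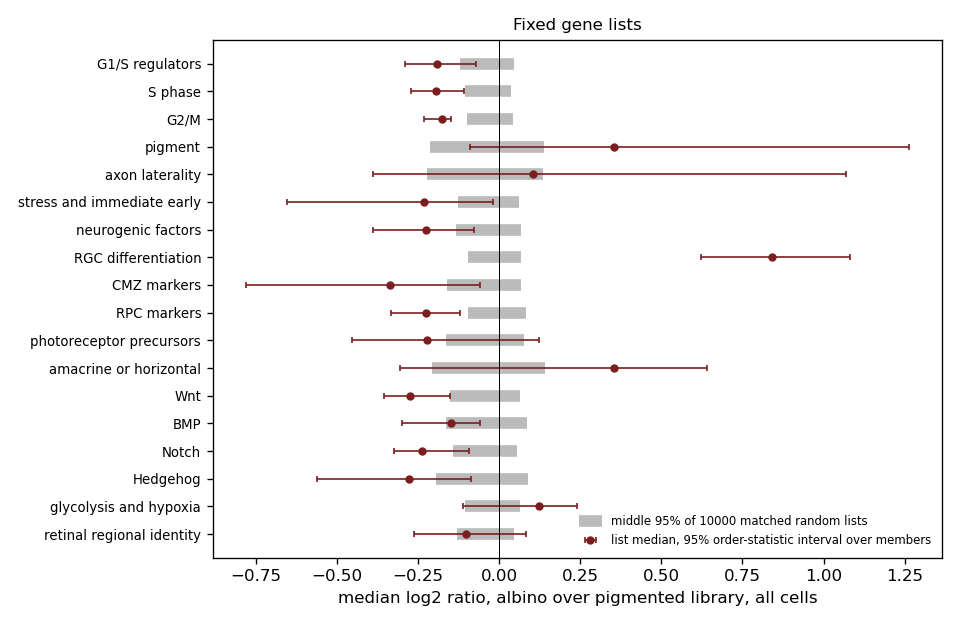
Median log2 ratio (albino over pigmented library, all cells) of each gene list fixed before the data were examined. Points carry 95% order-statistic intervals over the list's members, which are not replicates, and grey bars span the middle 95% of 10000 random lists matched on expression. The RGC differentiation list stands at 0.84, and the CMZ marker list at -0.34.

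The pigment genes were compared over all cells and in CMZ-like cells. Over all cells 9 of 11 were higher in the albino library (median log2 ratio 0.35). The tyrosinase gene Tyr stood at 1.52 CPM in the pigmented and 3.67 CPM in the albino library, Tyrp1 at 0.899 and 2.63, Dct at 12.1 and 17.1, Pmel at 15.7 and 22.4, Trpm1 at 31.4 and 37.4, Oca2 at 1.89 and 2.41, Slc45a2 at 0.320 and 0.597, Gpr143 at 0.229 and 0.288, Mlana at 2.19 and 2.06 and Mitf at 5.33 and 4.95. Slc24a5 stood at 137 and 151 CPM, and its exons overlap those of Myef2 on the opposite strand, so its value is uncertain. Pmel shares exon sequence with Cdk2 and Dgka and Trpm1 with Gm44722 in the same way. The unnamed cluster 19 (29 pigmented and 14 albino cells) held 77 of the 100 pigmented and 159 of the 166 albino Tyr UMIs, and there 1 albino cell held 60.2% of that library's Tyr UMIs and 51.0% of its Pmel UMIs. With every cell weighted equally the list's median was -0.54. Within CMZ-like cells 5 of 6 measured pigment genes were lower (median -0.68, or -0.14 with every cell weighted equally), with Trpm1 at 91.3 and 53.1 CPM, Mitf at 14.7 and 9.33, Dct at 10.3 and 4.67 and Pmel at 9.50 and 5.55, while Oca2 stood at 4.61 and 5.78 and Slc24a5 at 96.9 and 94.4 CPM.

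Genes tied to the crossing of RGC axons went both ways over all cells, 5 higher and 3 lower in the albino library. Zic2, a transcription factor gene of uncrossed RGCs that progenitors also express, stood at 43.3 and 33.1 CPM, Ephb1 at 4.63 and 3.69 and Boc at 4.33 and 3.56. The semaphorin and VEGF receptor gene Nrp1 stood at 10.1 and 21.3 CPM, Shh at 0.793 and 1.30, Plxna1 at 11.3 and 13.0 and Nrcam at 32.9 and 33.0, and Isl2 had a ratio of 1.72 (1.27 to 2.33). The median of 0.10 lay within the middle 95% of random lists. Within RGC-like cells the share of the class does not enter, but the make-up of the class by cluster can. Its clusters had unequal share ratios (1.84 and 2.40), and these genes were not split by cluster. There 4 of 7 measured genes were higher and the median was 0.02. Nrp1 stood at 58.6 and 80.5 CPM and Isl2 at 3.31 and 6.13 CPM, while Zic2 (17.8 and 16.8 CPM) and Ephb1 (6.62 and 6.61 CPM) differed by less than counting error. In CMZ-like cells Zic2 stood at 64.0 and 64.9 CPM. In neurogenic-like cells Zic2 was lower beyond counting error, at 46.5 and 27.4 CPM, a ratio of 0.589 (0.464 to 0.743). Its RPC-like ratio was 0.943 (0.853 to 1.04). Ephb1 was lower beyond counting error in RPC-like cells, at 5.95 and 3.73 CPM, a ratio of 0.628 (0.448 to 0.867). Its CMZ-like ratio was 0.672 (0.374 to 1.15).

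The UMIs of the genes with the largest ratios over all cells lay mostly in surface ectoderm-like and mesenchyme-like cells and in the unnamed cluster 12. The 10 ranked highest in the albino library were the keratin genes Krt15 (0.823 and 15.5 CPM) and Krt14, the connexin genes Gjb2 and Gjb6, the lens crystallin genes Cryaa, Cryba1, Crybb3 and Cryba2, the hormone subunit gene Cga and Krtap17-1. Of the albino Krt15 UMIs, 90.2% lay in the surface ectoderm-like cluster, and 89.0% of the albino Cryaa UMIs lay in the unnamed cluster 12. The 10 ranked lowest were Pf4 (10.7 and 0.0885 CPM), the endothelial genes Cdh5, Plvap and Aplnr, Ctla2a, Alox8, Mia, Ifitm1, Acta2 and Msx1. Of the pigmented Msx1 UMIs, 50.1% lay in CMZ-like cluster 5. Exons of Cga and Cryaa overlap gene models on the opposite strand, and Mia and Ctla2a share exon sequence with gene models on their own strand and are uncertain. For 9 of these 20 genes 1 cell held over 50% of a library's UMIs. Among cells that carry Xist and no Y-linked UMI, only 6 of the 20 were ranked again, and Cdh5, Ctla2a and Aplnr had log2 ratios of the opposite sign.

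Within CMZ-like cells the genes ranked lowest in the albino library were the calcium-binding protein gene S100a6 (45.8 and 14.0 CPM), Olfr889, Angptl4 (5.47 and 0.889 CPM), the kinase gene Sgk1 (83.6 and 41.1 CPM), which is among the leading genes of CMZ-like cluster 5, and the tachykinin gene Tac1 (13.7 and 5.11 CPM). The highest were Ptcra, Dqx1, Slc2a3 and the neuronal genes Stmn2 and Elavl4, of which 1 albino cell held 68.9% and 59.2% of the UMIs. In RPC-like cells S100a6, Msx1, Fosb (175 and 107 CPM), Zfp607a and Uap1l1 were ranked lowest, and Dqx1 (21.7 and 62.5 CPM), Ubash3a, Olfr1369-ps1, Xlr3b and Tfr2 highest. In neurogenic-like cells the lowest were Sult5a1, Tmem245, Spata7, Retn and the neurotrophin gene Ntf3 (23.3 and 10.6 CPM), and the highest Ptcra, Dqx1, Olfr889, H2-T23 and Creb5. In RGC-like cells Gng13, whose exons overlap those of Chtf18 on the opposite strand, Zfp202, P3h3, Slc25a20 and Cyba were ranked lowest and Dqx1 (8.70 and 38.7 CPM), Olfr889, Slc2a3, Prph and Olfr655 highest. Dqx1 was thus among the 5 highest in each of the 4 classes, but few cells carried its UMIs. In the pigmented and albino library these were 35 of 729 and 21 of 306 CMZ-like cells and 122 of 2157 and 55 of 1143 RPC-like cells. They were 32 of 551 and 31 of 322 neurogenic-like cells and 26 of 560 and 37 of 691 RGC-like cells. In CMZ-like cells 1 cell held 62.8% of the pigmented and 1 cell 40.7% of the albino Dqx1 UMIs. For 16 of these 40 entries 1 cell held over 50% of a library's UMIs in the class.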

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

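The tests of sex and of the CMZ marker score below were written before their results were seen, and the others were chosen after the result was seen.

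Cells outside the retina were present in both libraries although the sort was for TdTomato. Mesenchyme-like cells made up 3.73% of the pigmented and 3.60% of the albino cells, surface ectoderm-like cells 0.473% and 2.59%, and immune-like cells 0.455% and 0.835%. Y-linked UMIs were found in 48.7% of the pigmented cells, and in 3 albino cells. No gene of the outcome and pathway lists, out of 138 compared, had CMZ-like over RPC-like ratios in opposite directions in the 2 libraries beyond counting error.

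The RGC-like share was higher in the albino library. The sex of the pools as its whole cause is argued against, since among cells with Xist and no Y-linked UMI the ratio was still 1.78, with a lower bound of 1.51. A generally later stage of the albino embryos stays open. Photoreceptor-like and amacrine or horizontal-like cells together had a ratio of 0.842 (0.702 to 1.01), where a later stage was predicted to raise it. However, a larger RGC-like share lowers all other shares, and the unnamed clusters 2 and 10 were left out of that ratio. The amacrine or horizontal gene list was higher over all cells (median log2 ratio 0.35). Of its genes, Onecut1, Onecut2 and Tfap2b were higher beyond counting error, Ptf1a was lower (ratio 0.809, 0.736 to 0.888), and Prox1, Tfap2a and Lhx1 differed by less. Onecut2 UMIs lay in 2169 pigmented cells, while 140 pigmented cells were amacrine or horizontal-like. The level of Onecut2 can thus follow other classes, and the list does not settle the stage. Dissection or sorting that let in more central retina would lower the CMZ-like share as well, and that share had a ratio of 0.690 (0.602 to 0.790), so with 1 library per group it cannot be told apart from an effect of strain or pigmentation. The biological explanation by pigmentation stays open and untested.

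Ccnd2 was lower in the albino library. Fewer CMZ-like cells do not account for all of it, since within CMZ-like cells the ratio was 0.752 (0.699 to 0.808). Cluster make-up alone, with pigmented levels in every cluster, would give a log2 ratio of -0.43 of the -0.71 seen, and albino levels with pigmented make-up -0.20. Sex as the whole cause is argued against by a ratio of 0.652 (0.612 to 0.694) among cells with Xist and no Y-linked UMI, although within RPC-like cells the log2 ratio there was -0.03 against -0.23, so a part that goes with sex stays open, and a shift of the albino CMZ-like cells towards RPC-like cells as the whole cause by a ratio of 0.831 (0.784 to 0.881) when cells were matched on their CMZ marker score, although the ratio was below 1 beyond counting error in only 4 of the 10 bins of the score, stood at 1.01, 0.926, 0.963 and 0.915 in bins 6, 7, 8 and 10 and at 1.51 in bin 3, and a score from few UMIs matches cells only in part. Strain, pool, dissection and the biological explanation by pigmentation stay open, untested.

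Immediate early genes were lower in the albino library. A difference in handling between the libraries was assumed to act on every cell type, and that assumption was not tested. The highest class median was 1.23 (0.991 to 1.65), in immune-like cells, and the lowest 0.603, in surface ectoderm-like cells. Mesenchyme-like (1.10) and amacrine or horizontal-like cells (1.04) were also above 1. The intervals of the 3 classes above 1 reach 1, that of surface ectoderm-like cells does not, and handling cannot be told apart from a difference between the cells. A biological difference that goes with pigmentation or strain stays open, untested.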

How the results depend on the processing

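Of 138 results recomputed under 1013 combinations of result and setting, 895 stayed within the interval of the reported value, 111 moved beyond it and 7 turned direction from a value whose interval excluded 0. Values are log2 ratios of the albino over the pigmented library unless said otherwise, and the settings named here as to Xist, cell cycle genes, class markers, margins and retinal cells were added after the data were seen. The CMZ-like share ranged from -0.78 to -0.40, the RGC-like share from 0.70 to 1.05 (1.05 over retinal cells alone, 0.95 with doublets kept), and Ccnd2 in CMZ-like cells from -0.50 to -0.31. For the moved and turned values the cause was not tested. Depth limits the neurogenic-like Ccnd2 ratio, which rests on 97 and 28 UMIs.

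With cells that carry Xist and no Y-linked UMI, the CMZ-like share of cells was -0.7809, the RGC-like share of cells 0.8305, Ccnd2 in all cells -0.6177 and Ccnd2 in RPC-like cells -0.0296, and 6 of the 20 genes of the ranking were kept. All 7 of these turned results arose there: Cdh5 2.61, Ctla2a 1.481 and Aplnr 1.803 over all cells, Tmem245 0.7928 and Retn 2.001 in neurogenic-like cells, Slc25a20 0.1001 in RGC-like cells and the Wnt list 0.09803 in neurogenic-like cells. The RPC-like share of cells was -0.03315 with at least 1000 genes per cell and -0.0168 with a naming margin of 0.5, where Ccnd2 in RPC-like cells was -0.3873. Classes from marker scores gave 0.8352 for the RGC-like share and, for Ccnd2, -0.01493 in RPC-like and -0.3163 in neurogenic-like cells. Ccnd2 in neurogenic-like cells was -0.2781 without cell cycle genes in the clustering (RGC-like share 0.7048), -0.3787 without class markers and -0.4656 with genes centred within each library. With every cell weighted equally, Ccnd2 over all cells was -0.6394, the G2/M list -0.06807 and the pigment list -0.5426, a change of sign from 0.35, whose interval included 0, and 12 of the 20 ranked genes were kept, as with at least 200 UMIs (12). Median-of-ratios scaling gave -0.1244 for the G2/M list. After thinning, a Ccnd2 UMI was found in 19.6% of all pigmented and 14.3% of all albino cells. At least 2 Ccnd2 UMIs were found in 10.3% and 6.54% of all cells, a log2 ratio of -0.6572.

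The log2 ratio of Ccnd2 in CMZ-like over RPC-like cells, pigmented, was 2.49, and that of Ccnd2 in CMZ-like over RPC-like cells, albino, 2.31. They were 2.014 and 1.886 at Leiden resolution 0.5 and 2.73 and 2.522 at 2.0, 2.311 and 2.098 with at most 5% mitochondrial UMIs, 2.87 and 2.81 with at least 1000 genes, 2.823 and 2.768 without cell cycle genes, 2.736 and 2.467 with equal weights and 2.617 and 2.593 with a margin of 0.5. In the pigmented library it was also 2.6 with all variable genes, 2.606 with marker scores and 2.659 in the Xist-carrying cells, and in the albino library 2.141 with doublets kept.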

Other observations

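Genes of the regional list, chosen before the data were examined, went both ways within CMZ-like cells. Tbx3 (21.0 CPM in the pigmented and 37.5 CPM in the albino library), Tbx2 (26.9 and 41.1), Efnb2 (67.4 and 91.3), Efnb1 (11.5 and 15.8), Epha5 (217 and 263) and Aldh1a1 (832 and 1049 CPM), which is among the leading genes of both CMZ-like clusters, were higher in the albino library beyond counting error. Aldh1a3 (228 and 170 CPM), Vax2 (67.8 and 58.2 CPM) and Efna5 (112 and 98.2 CPM) were lower beyond counting error. Tbx5 (13.2 and 17.3 CPM), Bmp4 (12.3 and 10.9), Vax1 (3.74 and 2.89), Ephb3 (7.10 and 5.78), Ephb2 (34.5 and 40.4) and Foxd1 (66.5 and 61.5 CPM) differed by less than counting error. The list's median log2 ratio in CMZ-like cells was 0.25, above the middle 95% of random lists, but 0.00 with every cell weighted equally. It was 0.00 in RPC-like cells and -0.10 over all cells, both within that range. The genes of this list do not all mark the same region, so its median cannot show a shift between regions. Whether the sampled tissue differed by region between the libraries was not tested.

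The pigmented pool allows a comparison of cells from different embryos of 1 library, since cells with Y-linked UMIs and no Xist and cells with Xist and no Y-linked UMIs come from different animals. CMZ-like cells were 13.0% of the 2633 former and 15.6% of the 1672 latter cells, RGC-like cells 9.38% and 11.5%, and neurogenic-like cells 11.2% and 8.91%. Ccnd2 stood at 99.6 CPM (96.2 to 103) in the former and 85.5 CPM (81.4 to 89.7) in the latter over all cells, and at 300.4 (285 to 316) and 286 CPM (269 to 304) in CMZ-like cells and 56.9 (52.6 to 61.5) and 45.3 CPM (40.6 to 50.4) in RPC-like cells. Sex and embryo are confounded here, and the all-cell and RPC-like values differ by more than counting error while the CMZ-like values do not.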
